A study of Mus musculus with 9 samples.

How the data were processed

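Expression was measured on Illumina bead arrays in 9 retinal samples from C57BL/6N mice, 3 per group, each from the pooled 2 retinas of 1 mouse. Per the labels' protocols, RNA was extracted with chloroform and isopropanol, and biotin-labelled cRNA was made with an Ambion kit for Illumina arrays. The scanner software, the handling of beads and the background treatment are not given in the sources used here.

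The deposited raw table holds a probe intensity per array on a linear scale, with no negative value and with medians that differ between arrays, so it was treated as neither background-corrected nor normalized. Beside each intensity the deposited table holds a detection p-value, as its header names it. All 81 pairs of a p-value column and an intensity column were tested, and each p-value column never rose with the intensity of exactly 1 array, while with any other array it rose at 2.46% of steps or more. For 5 arrays (control 2 and 3 and all hyperoxic arrays) the matching column was not the one beside the intensity. The p-values were used with the array they follow. The deposited value table holds a ratio per probe and array on a linear scale, and the scaling the authors used before forming it is not given in the sources used here. All 84 sets of 3 arrays were tested for a median ratio of 1 within 0.0015. Each ratio column followed the intensities of its own array (r = 0.946 to 0.980, at most 0.616 with any other). Median ratios were 0.903 on hyperoxic 1 and 0.996 to 1.01 on the other arrays. The ratios were used only as an alternative.

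Of 46640 probes, 27 were at 0 on all arrays and were left out. Of the 46613 analysed, 32781 had 1 gene symbol in the platform annotation given, 55 had several and 13777 had none, and 32709 were matched to a current gene identifier. Probes with several symbols were not named. Gene symbols were updated through these identifiers.

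Intensities were corrected and normalized with neqc from limma 3.58.1 in R 4.3.3, which fits a normexp background to negative controls inferred from the detection p-values, adds an offset of 16 and applies quantile normalization on the log2 scale. The offset makes fold changes of dim genes smaller than they are. Probes with a detection p under 0.05 on all arrays of at least 1 group were tested (19620). All 9 arrays entered 1 linear model (lmFit and eBayes) with a mean per group, and contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for genes come from limma. A probe detected on no array of a group has only a bound there, and its change is given as at least N-fold, against the lowest signal detected on those arrays or the probe's own value where higher. The number of arrays limits the precision.

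Gene lists were tested with camera at a preset correlation of 0.01 on the most intense probe of each gene, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. The 32 lists covered glycolysis, HIF targets outside glycolysis, angiogenic ligands and receptors, basement membrane, reactive gliosis and the LIF/STAT3 response, proliferation, NRF2 and antioxidant genes, immediate early genes, circadian clock, the unfolded protein and ATF4 response, cholesterol synthesis, oxidative phosphorylation, heat shock proteins, p53 targets and cell death, inflammatory cytokines and NF-kB targets, and interferon-stimulated genes. They also covered markers of endothelial cells, pericytes and vascular smooth muscle, Muller glia, astrocytes, rods, cones, bipolar, amacrine, ganglion and horizontal cells, microglia and macrophages, oligodendrocytes and myelin, erythroid cells, pigment epithelium and melanocytes, lens crystallins, and lens genes other than crystallins. The last had 3 tested genes, under the minimum of 5, so 31 were tested. Some genes belong to several lists, such as Mt1, Igfbp3 and Stc2.

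The comparisons, tests, lists, the rule for naming genes and most alternatives were fixed before the data were examined. By the rule, the text names for each comparison the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between groups, leaving out clone names, up to 4 members of lowest p from each list, and 13 genes whatever their values, of which 1 is not reported here. For genes with several tested probes the most intense was used. The probes of named genes had the same sign except for Hsp90aa1 between the P12 groups, Egln3 against the control and Abca4 against all 6 P12 arrays. The comparison of P12.5 with all 6 P12 arrays, named by the same rule, was added afterwards.

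The pipeline was tested on simulated data with known changes in 19620 probes. It recovered 26.9%, 76.1% and 95.5% of changes of 1.5-, 2- and 3-fold between hyperoxic and control, 22.4%, 83.6% and 95.5% between P12.5 and hyperoxic, and 16.4%, 80.6% and 97.0% between P12.5 and control. With no change simulated it called 0 probes. Wrong calls were 8 of 140, 11 of 145 and 8 of 137. The overlap of calls was set beside 50 simulations of unchanged groups. In all simulations the noise was independent between probes and arrays. These rates therefore do not cover structure shared by many probes of an array.

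Alternatives were quantile normalization without background correction, median centring, the deposited ratios on a log2 scale, no detection filter, detection on all 9 arrays, a trended robust variance, array weights, only the compared groups in the fit, the replicate number as a block, 1 probe per gene before adjustment and leaving out each array. Added after the data had been seen were the p-values in their deposited positions, normexp with an offset of 50, leaving out 4 arrays whose labels are in doubt, and grouping the P12 arrays by the deposited ratios. Counts of calls lost under alternatives leave out these added alternatives. No chip record was given, so chips could not be examined as batches. No sample was left out of the comparisons.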

Results

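Gene expression was measured in whole retinas of C57BL/6N mice under oxygen-induced retinopathy. In this model high oxygen halts and prunes the growing retinal vessels of newborn mice, and room air then leaves the poorly perfused tissue short of oxygen. Pups and their mothers were kept in 75 ± 2% oxygen from postnatal day 7 (P7) for 5 days. The hyperoxic group was sampled on leaving the chamber at P12, the hypoxic group after 12 hours in room air at P12.5, and the control group consisted of normal P12 mice. Each group had 3 arrays, and each array carried RNA from both retinas of 1 mouse, 9 mice in all, which the design text calls biological replicates. Normal mice of P12.5 were not among the samples, so every comparison with P12.5 also spans 12 hours of age and time of day. By high Xist and low Eif2s3y, control 1, control 3 and hypoxic 2 had a female pattern. The labelled groups were thus not balanced for sex, and sex was not a term in their comparisons.

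Of 46613 probes, 19620 were detected on all arrays of at least 1 group and were tested, and 15546 of these had a gene name, covering 10948 genes. Median intensity lay between 67.4 and 82.3 on 8 arrays and was 163.6 on hyperoxic 1. On hyperoxic 1, 30.6% of probes were detected, against 42.1% to 44.5% on the other arrays, and its mean correlation with the others was 0.963, against 0.977 to 0.983. The deposited ratios had a median of 1 (within 0.0015) over control 1, hyperoxic 2 and hyperoxic 3 at 100% of probes. Over the arrays labelled control the same held at 12.6% of probes, and the next best of the 84 sets of 3 arrays reached 42.7%. The detection p-value columns placed beside the 3 control signals belonged to control 1, hyperoxic 2 and hyperoxic 3, judged by which signal each column followed. These observations leave the labels of control 2 and 3 and hyperoxic 2 and 3 in doubt. Conditions are nevertheless given throughout as the arrays are labelled, and a possible exchange of labels is taken up below.

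The first comparison addressed the state of the retina at the end of the oxygen phase. No single gene passed the test between the arrays labelled hyperoxic and those labelled control. Split by the deposited reference instead, the same P12 arrays differed at 783 probes. The absence of calls therefore holds for the labels and does not show that oxygen left expression unchanged. The angiogenic factor Vegfa differed by 0.00 ± 0.18 (log2 difference ± SE from limma, 3 arrays per group, as for the gene values of the labelled comparisons that follow). The glucose transporter Slc2a1 differed by -0.05 ± 0.12, the vasodilator peptide Adm by 0.04 ± 0.15, the vessel-destabilising ligand Angpt2 by -0.01 ± 0.12 and the heme oxygenase Hmox1 by -0.12 ± 0.17. The endothelial adhesion molecule Pecam1 differed by 0.16 ± 0.50, the glial filament gene Gfap by -0.22 ± 0.14, and the clock genes Per2 and Dbp by 0.21 ± 0.15 and 0.29 ± 0.12. Epo and Apln were not detected on any array, and Cldn5 had no named probe.

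In that comparison 8 of 31 gene lists lay higher as groups in the arrays labelled hyperoxic by camera, although 0 of their 168 tested members passed over all probes and none of the 8 held with an estimated correlation (camera adjusted p = 0.452 to 0.668). Grouped by the deposited ratios, the endothelial, pericyte and heat shock lists passed as lower and the others did not pass. The counts of lost calls below leave out that grouping. The 14 lens crystallins, structural proteins of the lens, had a median difference of 1.40 (camera adjusted p = 2.03e-05), with Cryba1 at 1.79 ± 0.90 and Cryaa at 1.29 ± 0.72, and 0 passed adjusted over the list alone. Without hyperoxic 1 that median was 0.44 and the list did not pass (camera adjusted p = 0.21). The 12 cone genes had a median of 0.20 (camera adjusted p = 0.00205), and the transducin subunit Gngt2 (0.38 ± 0.10) passed adjusted over the list alone, while Pde6h was at 0.36 ± 0.14. The 43 genes of oxidative phosphorylation had a median of 0.05 (camera adjusted p = 0.00512), and the complex I subunit Ndufb10 (0.59 ± 0.13) passed adjusted over the list alone, with Ndufb5 at 0.35 ± 0.13. That list did not pass without control 1 (median 0.03) or hyperoxic 1 (median -0.07, of the other sign). The 30 endothelial genes had a median of 0.26 (camera adjusted p = 0.00805), but members lay both ways, with Ramp2 at 0.53 ± 0.30, Cav1 at 0.43 ± 0.26 and the VEGF receptor Kdr at -0.35 ± 0.20. The endothelial median was 0.57 without control 1 and 0.67 without hyperoxic 1, but 0.08, 0.09, 0.15 and 0.05 without control 2, control 3, hyperoxic 2 and hyperoxic 3, and in these 4 settings the list did not pass. The 11 pericyte and smooth muscle genes had a median of 0.25 (camera adjusted p = 0.0288), and the connexin Gjc1 (0.52 ± 0.10) passed adjusted over the list alone, with Vtn at 0.56 ± 0.22. The pericyte list failed in the same 4 settings, at 0.02, 0.13, 0.02 and 0.01, against 0.40 and 0.48 without control 1 and hyperoxic 1. Heat shock genes (17 tested, median 0.21, camera adjusted p = 0.0124) included Hspe1 at 0.53 ± 0.20 and Hsp90aa1 at 0.59 ± 0.23. Ganglion cell genes (18 tested, median 0.14, camera adjusted p = 0.0142) included Nefh at 0.34 ± 0.13 and Gap43 at 0.33 ± 0.13. Rod genes (23 tested, median 0.10, camera adjusted p = 0.015) included Guca1a at 0.40 ± 0.14 and Reep6 at 0.29 ± 0.11. For heat shock, ganglion cell and rod genes 0 members passed adjusted over the list alone. The heat shock and rod lists did not pass without control 2, control 3, hyperoxic 2 or hyperoxic 3, nor the ganglion cell list without hyperoxic 1 or hyperoxic 2, while the cone list passed without any 1 array. With the deposited ratios the median of all probes was -0.15, against -0.06 as reported. Under them rods (-0.13), cones (-0.06), ganglion cells (-0.12) and heat shock (-0.01) had negative medians that lay above that shift, oxidative phosphorylation (-0.22) lay below it, and of these 5 lists only cones passed. Oxidative phosphorylation also had a negative median with median centring (-0.01), above the -0.12 of all probes. Over the alternatives run on lists the calls were lost under 4 of 17 for crystallins, 2 of 17 for cones, 6 of 17 for oxidative phosphorylation, 6 of 17 for endothelial, 6 of 17 for pericyte, 7 of 17 for heat shock, 6 of 17 for ganglion cell and 7 of 17 for rod genes.

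Over all 19620 probes limma called 0 between these groups (lowest adjusted p = 0.458), while 1873 had an unadjusted p under 0.05, against 981 expected by chance. Without hyperoxic 1, 568 probes passed (470 higher and 98 lower in the arrays labelled hyperoxic), without control 1 a single probe did, and with array weights 2680 did. In the fit without hyperoxic 1 the arrays left as hyperoxic were hyperoxic 2 and 3, both of the deposited reference. Those 568 calls therefore cannot be told apart from the split along that reference. By fry 1 of the 8 lists passed, the ganglion cell list (adjusted p = 0.0172). The number of lists passing fell to 4 without control 2, control 3 or hyperoxic 3, to 3 without hyperoxic 2 and to 5 without hyperoxic 1. Within each labelled P12 group the vascular markers were spread widely. The mean log2 level of the endothelial genes was 7.63 to 7.73 on control 1, hyperoxic 2 and hyperoxic 3 and 6.74 to 6.85 on control 2, control 3 and hyperoxic 1. For pericyte genes these ranges were 7.08 to 7.14 and 6.38 to 6.54, and for Pecam1 7.57 to 7.74 and 5.68 to 6.43.

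**Figure D1:**
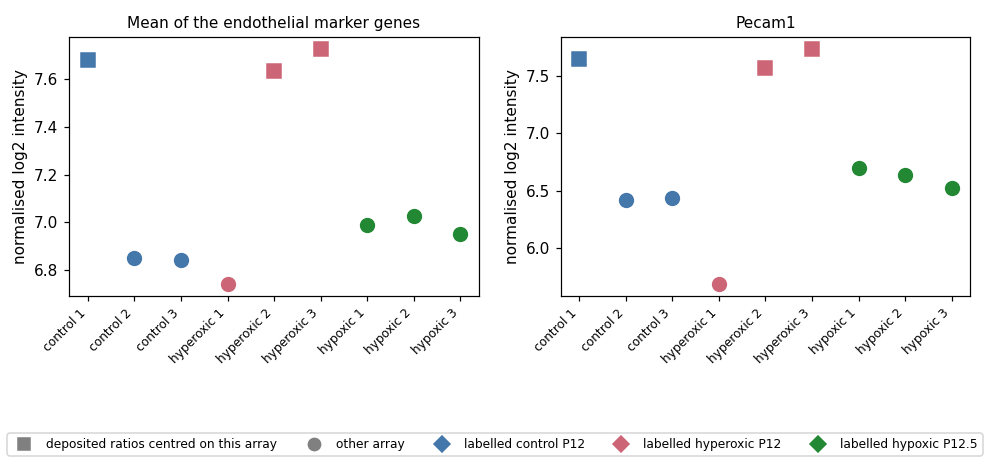
Mean normalized log2 intensity of the endothelial marker genes and of Pecam1 on each of the 9 arrays, with points coloured by the deposited label and squares for the 3 arrays on which the deposited ratios are centred. The squares lie at 7.63 to 7.73 for the marker mean, the other 3 P12 arrays at 6.74 to 6.85 and the P12.5 arrays at 6.95 to 7.03.

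The second comparison addressed the first 12 hours in room air, setting the P12.5 arrays against the arrays labelled hyperoxic. Genes of the hypoxia response and of reactive gliosis were among those that rose, and cone and rod genes were among those that fell. The largest rises were in the MHC class II chain H2-Ab1 (2.56 ± 0.26), the chemokine Ccl4 (at least 3.14-fold, adjusted p = 5.26e-04 by limma), the growth factor binding protein Igfbp3 (1.93 ± 0.24) and the TWEAK receptor Tnfrsf12a (1.90 ± 0.19). They were followed by the MHC class I gene H2-Q6 (at least 2.27-fold), the cell cycle inhibitor Cdkn1a (1.80 ± 0.22), the stress regulator Nupr1 (1.79 ± 0.36) and the mucin Muc5ac (1.70 ± 0.15). The largest falls were in cone arrestin Arr3 (-2.26 ± 0.29, adjusted p = 0.00657 by limma), the endothelial thyroxine transporter Slco1c1 (-1.73 ± 0.32), the ubiquitin ligase Peli3 (-1.42 ± 0.20) and vitronectin, Vtn (-1.30 ± 0.22). The guanylate cyclase activator Guca1b (-1.27 ± 0.15), the phosphate transporter Slc17a1 (-1.23 ± 0.26), the glucokinase regulator Gckr (-1.16 ± 0.19) and the synaptic protein gene Unc13c (-1.01 ± 0.16) also fell. H2-Q6 has close paralogs, so its probe may detect more than 1 gene. Ccl4 and H2-Q6 are ranked here and in the later comparisons by measured values that include undetected arrays, so their places are uncertain. H2-Ab1 was detected on only 6 arrays of the study and Igfbp3 on 7. The sizes and places of the rises of H2-Ab1 and Igfbp3 are therefore uncertain too, here and in the later comparisons.

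Among genes followed whatever their values, Adm (1.22 ± 0.15), Hmox1 (1.31 ± 0.17), Gfap (0.69 ± 0.14) and Slc2a1 (0.64 ± 0.12) rose, though the calls of Gfap and Slc2a1 were each lost under 10 of 16 alternatives. Vegfa at 0.70 ± 0.18 (adjusted p = 0.0896 by limma) and Angpt2 at 0.42 ± 0.12 (adjusted p = 0.104 by limma) did not pass, nor did Pecam1 (-0.38 ± 0.50), Per2 (-0.22 ± 0.15) or Dbp (-0.33 ± 0.12). Of 38 targets of the hypoxia-inducible factors outside glycolysis, 9 rose, 0 fell and 29 did not pass, with 22 up and 2 down adjusted over the list alone. The prolyl hydroxylase Egln3 (1.54 ± 0.16) and the metallothionein Mt1 (1.54 ± 0.16) were among those that rose. The median was 0.48 (camera adjusted p = 1.13e-07; adjusted p = 0.217 with an estimated correlation). Of 19 glycolysis genes 4 rose, 0 fell and 15 did not pass, with 5 up and 1 down adjusted over the list alone. Those that rose were the pyruvate dehydrogenase kinase Pdk1 (1.54 ± 0.12), hexokinase Hk2 (0.90 ± 0.18), Pfkfb3 (0.77 ± 0.14) and Slc2a1. The list had a median of 0.22 (camera adjusted p = 9.63e-04; adjusted p = 0.217 with an estimated correlation). Of 22 genes of reactive gliosis and the LIF/STAT3 response 7 rose, 0 fell and 15 did not pass, with 10 up and 0 down adjusted over the list alone, including the oncostatin M receptor Osmr (1.28 ± 0.18), ceruloplasmin Cp (0.74 ± 0.13) and the filament gene Nes (at least 1.36-fold). The median was 0.38 (camera adjusted p = 3.89e-07), and this list also passed with an estimated correlation (adjusted p = 0.0409).

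Of 20 immediate early genes, 3 rose, 0 fell and 17 did not pass, with 5 up and 1 down adjusted over the list alone and a median of 0.20 (camera adjusted p = 0.00409; adjusted p = 0.298 with an estimated correlation). Those that rose were the matricellular gene Ccn2 (1.26 ± 0.14) and the AP-1 subunits Fosl2 (1.35 ± 0.21) and Jun (0.79 ± 0.13). Of 26 genes of the unfolded protein and ATF4 response 1 rose, 0 fell and 25 did not pass, with 4 up and 0 down adjusted over the list alone, at a median of 0.22 (camera adjusted p = 0.0498; adjusted p = 0.217 with an estimated correlation). Stc2 (0.89 ± 0.12), which is also in the HIF target list, rose, and the serine pathway enzyme Shmt2 lay at 0.70 ± 0.18. Of 8 inflammatory genes 2 rose, 0 fell and 6 did not pass, with 2 up and 1 down adjusted over the list alone, Ccl4 and the chemokine Ccl3 (at least 1.33-fold). Their median was 0.24 (camera adjusted p = 0.0498; adjusted p = 0.33 with an estimated correlation). The inflammatory list did not pass without hyperoxic 1 (median 0.17) or hypoxic 2, and of the fits leaving out 1 array the unfolded protein list passed only without hyperoxic 2. Over the alternatives run on lists the inflammatory call was lost under 8 of 16, the unfolded protein call under 8 of 17 and the crystallin call under 9 of 17. The 14 lens crystallins had a median of 0.93 with 0 passing over all probes or adjusted over the list alone (Cryga 1.83 ± 0.88, camera adjusted p = 0.0498; adjusted p = 0.758 with an estimated correlation). That median was 1.91 without hyperoxic 1, and 0.56, 0.37 and 0.11 without hyperoxic 2, hyperoxic 3 and hypoxic 1, where the list did not pass.

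Of 12 cone genes, 0 rose, 3 fell and 9 did not pass, with 0 up and 3 down adjusted over the list alone, namely Arr3, the opsin Opn1mw (-0.88 ± 0.10) and Pde6h (-0.71 ± 0.14). Of 23 rod genes 0 rose, 2 fell and 21 did not pass, with 0 up and 7 down adjusted over the list alone, Guca1b and the rod transducin Gnat1 (-0.55 ± 0.11). Of 17 bipolar cell genes Lrtm1 (-0.66 ± 0.13) fell and 16 did not pass, with 0 up and 5 down adjusted over the list alone. Of 17 genes of cholesterol synthesis Sc5d (-0.61 ± 0.12) fell and 16 did not pass, with 0 up and 1 down adjusted over the list alone. The medians were -0.17 for cones (camera adjusted p = 0.00283), -0.12 for rods (camera adjusted p = 2.65e-04), -0.25 for bipolar cells (camera adjusted p = 0.0143) and -0.19 for cholesterol synthesis (camera adjusted p = 8.48e-04), and all 4 were positive with median centring (0.05, 0.20, 0.04 and 0.14) and with the deposited ratios (0.00, 0.24, 0.12 and 0.06), under which the median of all probes was 0.31 and 0.20. Relative to these shifts the medians lay lower, except that of rods with the deposited ratios, and all 4 lists passed camera as lower under both scalings. With an estimated correlation these 4 lists had camera adjusted p = 0.217, 0.217, 0.353 and 0.226. Of 30 endothelial genes Slco1c1 fell and 29 did not pass, with 0 up and 1 down adjusted over the list alone and a median of -0.37 (camera adjusted p = 0.00876; adjusted p = 0.689 with an estimated correlation). The endothelial median was -0.74 without hyperoxic 1, and -0.29 and -0.19 without hyperoxic 2 and hyperoxic 3, where the list did not pass. It was -0.15 with median centring and -0.15 with the deposited ratios, not corrected for the shift of all probes, and the list passed under both. The direction depended on the labels: against control 2, control 3 and hyperoxic 1, outside the deposited reference, the endothelial median at P12.5 was 0.17, higher (camera adjusted p = 0.0292; adjusted p = 0.295 with an estimated correlation). Of 12 genes of the pigment epithelium and melanocytes 0 passed over all probes, with 0 up and 3 down adjusted over the list alone (Rdh5 -0.56 ± 0.14) and a median of -0.20 (camera adjusted p = 0.0173; adjusted p = 0.353 with an estimated correlation). This median was -0.07 and -0.04 under those 2 scalings, where the list passed, but it did not pass without hyperoxic 2 or hypoxic 3, nor the bipolar list without hyperoxic 2 or hypoxic 1. Over the alternatives run on lists the calls of bipolar, endothelial and pigment epithelium genes were lost under 4 of 17, 4 of 17 and 5 of 17. These counts leave out the grouping by the deposited ratios, under which rods, cones, bipolar cells and cholesterol synthesis did not pass.

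**Figure D2:**
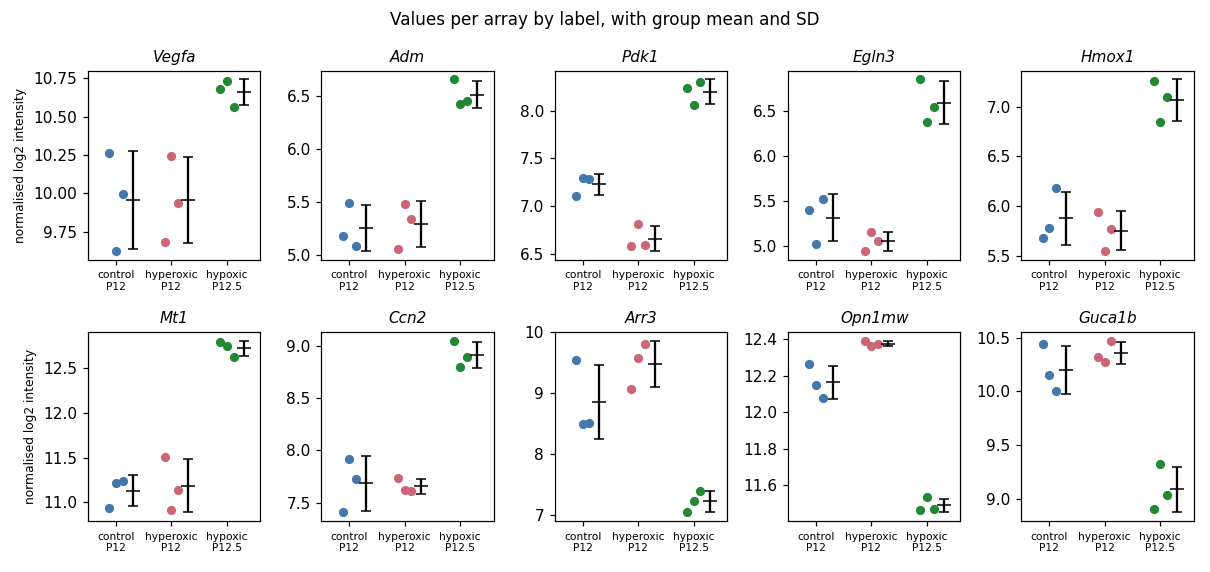
Normalized log2 intensity of 10 genes on each array by label, with the group mean and SD over 3 arrays. Adm (1.22 against the arrays labelled hyperoxic), Pdk1 (1.54), Egln3 (1.54), Hmox1 (1.31), Mt1 (1.54) and Ccn2 (1.26) were higher at P12.5, Arr3 (-2.26), Opn1mw (-0.88) and Guca1b (-1.27) were lower, and Vegfa (0.70) did not pass the test.

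In all, limma called 333 probes between P12.5 and the arrays labelled hyperoxic, 222 higher and 111 lower at P12.5, of which 211 and 90 changed at least 1.5-fold. They covered 214 genes, 131 higher and 83 lower. Many gene calls were lost under alternatives. Besides Gfap and Slc2a1, the most frequent losses were 10 of 16 for Slco1c1, Slc17a1, Hk2, Pde6h, Gnat1 and Sc5d, 9 of 16 for Vtn, Pfkfb3 and Lrtm1, 8 of 16 for Nupr1. With median centring the split was 182 higher and 3 lower, and with the deposited ratios 21 and 0. Under these scalings the median change of all probes, relative to which single changes are read, was 0.31 and 0.20, against 0.05 as reported. The count was 2006 without hyperoxic 1, 95 without hyperoxic 3, and 49, 89 and 54 without hypoxic 1, 2 and 3. It was 5289 with array weights, 109 with only these groups in the fit and 190 with no detection filter. Without hyperoxic 1 the arrays left as hyperoxic both belong to the deposited reference, so the 2006 calls also carry that split.

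The third comparison set P12.5 against the arrays labelled control. Genes of the hypoxia response and of gliosis were among those that rose here too, and cone genes were among those that fell. Ccl4 (at least 3.75-fold, adjusted p = 6.75e-04 by limma), H2-Ab1 (2.04 ± 0.26), Nupr1 (2.03 ± 0.36), Tnfrsf12a (1.82 ± 0.19), Igfbp3 (1.72 ± 0.24), H2-Q6 (at least 2.71-fold), Cdkn1a (1.69 ± 0.22) and Hif1a (1.61 ± 0.27), which encodes the oxygen-regulated subunit of HIF-1, rose most. Arr3 (-1.63 ± 0.29, adjusted p = 0.0262 by limma), Tmem267 (-1.41 ± 0.22), Peli3 (-1.33 ± 0.20), Thap2 (-1.11 ± 0.21), Guca1b (-1.11 ± 0.15), Rdm1 (-1.09 ± 0.15), the phospholipase Plcd3 (-1.01 ± 0.19) and Gckr (-0.97 ± 0.19) fell most. Many of these calls were lost under the alternatives run on them. For genes named against control the most frequent losses were 10 of 16 for Arr3, Thap2, Plcd3 and Gckr, 10 of 15 for Fosl2 and Ccl3, 9 of 16 for Rdm1, Stat3, Opn1mw, Pde6b and Bhlhe40, 9 of 15 for Osmr, 8 of 16 for Nupr1, Tmem267 and Peli3, 8 of 15 for Hif1a and Stc2. Adm (1.26 ± 0.15), Hmox1 (1.19 ± 0.17) and Slc2a1 (0.59 ± 0.12) rose, with calls lost under 4 of 15, 6 of 16 and 10 of 16 alternatives. Vegfa at 0.70 ± 0.18 (adjusted p = 0.0844 by limma), Angpt2 at 0.41 ± 0.12, Gfap at 0.47 ± 0.14, Pecam1 at -0.22 ± 0.50, Per2 at -0.02 ± 0.15 and Dbp at -0.05 ± 0.12 did not pass.

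Of 38 HIF targets outside glycolysis, 12 rose, 0 fell and 26 did not pass, with 19 up and 0 down adjusted over the list alone, among them Egln3 (1.28 ± 0.16), its relative Egln1 (1.04 ± 0.14), Mt1 (1.59 ± 0.16) and the repressor Bhlhe40 (0.88 ± 0.13). The median was 0.43 (camera adjusted p = 5.94e-09; adjusted p = 0.196 with an estimated correlation). Of 19 glycolysis genes 2 rose, 0 fell and 17 did not pass, with 7 up and 0 down adjusted over the list alone. Pdk1 (0.97 ± 0.12) and Slc2a1 rose, and Hk2 lay at 0.76 ± 0.18. The list median was 0.29 (camera adjusted p = 9.49e-04; adjusted p = 0.236 with an estimated correlation). Of 22 gliosis genes 5 rose, 0 fell and 17 did not pass, with 10 up and 0 down adjusted over the list alone, including Nes (at least 1.63-fold), Osmr (1.05 ± 0.18) and the transcription factor Stat3 (0.55 ± 0.11). Their median was 0.42 (camera adjusted p = 8.39e-07), and the list passed with an estimated correlation too (adjusted p = 0.0497). Of 20 immediate early genes 2 rose, 0 fell and 18 did not pass, with 6 up and 1 down adjusted over the list alone, Ccn2 (1.23 ± 0.14) and Fosl2 (adjusted p = 0.0492 by limma), at a median of 0.26 (camera adjusted p = 1.27e-04; adjusted p = 0.236 with an estimated correlation). Of 26 genes of the unfolded protein and ATF4 response 1 rose, 0 fell and 25 did not pass, with 5 up and 1 down adjusted over the list alone. Stc2 (0.82 ± 0.12), also in the HIF target list, rose and Shmt2 lay at 0.75 ± 0.18. The list median was 0.31 (camera adjusted p = 0.00306, and 0.133 with an estimated correlation).

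Of 8 inflammatory genes, 2 rose, 0 fell and 6 did not pass, with 3 up and 1 down adjusted over the list alone, Ccl4 and Ccl3 (at least 1.59-fold), at a median of 0.27 (camera adjusted p = 0.0205; adjusted p = 0.319 with an estimated correlation). The 14 crystallins had a median of 2.37 (1.56 without hypoxic 1; camera adjusted p = 8.39e-07; adjusted p = 0.571 with an estimated correlation). None passed over all probes and 9 were higher adjusted over the list alone, with Cryga at 3.21 ± 0.88 and Cryaa at 2.40 ± 0.72. Their mean log2 level was 6.15 ± 0.50 (SD, n = 3) on the control, 7.39 ± 1.45 on the hyperoxic and 8.39 ± 1.39 on the P12.5 arrays, and over the 9 arrays it followed the mean of 3 other lens genes (r = 0.900, exact permutation p = 0.000521; rho = 0.917, exact permutation p = 0.00131; r = 0.717 without the 2 arrays farthest from the median). On most arrays the mean of these other lens genes lay near the level of undetected probes. The 12 pigment epithelium and melanocyte genes had a median of -0.34 (camera adjusted p = 0.0159; adjusted p = 0.536 with an estimated correlation). None of them passed over all probes, with 0 up and 6 down adjusted over the list alone, and the melanocyte genes Dct and Pmel lay at -0.62 ± 0.14 and -0.62 ± 0.16. The median was -0.21 without hypoxic 3, where the list did not pass. It was -0.20 with median centring and -0.14 with the deposited ratios (all probes 0.18 and 0.05), where it passed. Opn1mw (-0.67 ± 0.10) and the rod phosphodiesterase Pde6b (-0.46 ± 0.09) fell, though the cone and rod lists did not pass in this comparison. Over the alternatives run on lists the list calls were lost under 2 of 16 for inflammatory genes, 2 of 17 for crystallins and 3 of 17 for the pigment epithelium. These counts leave out the grouping by the deposited ratios, under which the inflammatory list did not pass.

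**Figure D3:**
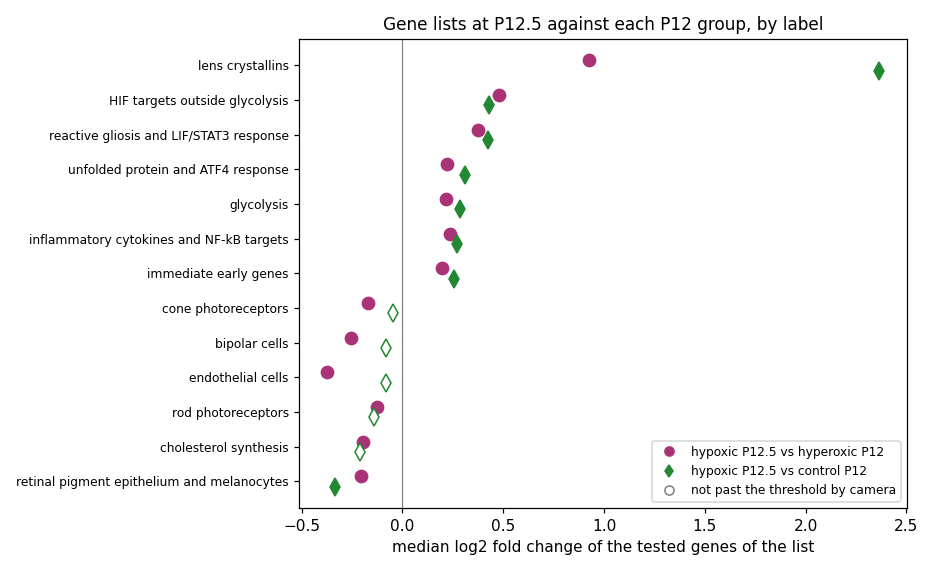
Median log2 difference of 13 gene lists at P12.5 against the arrays labelled hyperoxic (circles) and against those labelled control (diamonds), open where camera did not pass the list. HIF targets lie at 0.48 and 0.43, gliosis genes at 0.38 and 0.42 and crystallins at 0.93 and 2.37, while the negative medians of rods, cones, bipolar cells and cholesterol synthesis against hyperoxic are positive with median centring and with the deposited ratios, which move the median of all probes to 0.31 and 0.20, above these medians except that of rods (0.24) with the deposited ratios. They pass as lower at the preset correlation under both scalings and not with an estimated one (camera adjusted p = 0.217, 0.217, 0.353 and 0.226).

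In this comparison limma called 371 probes, 253 higher and 118 lower at P12.5, of which 221 and 83 changed at least 1.5-fold. They covered 251 genes, 167 higher and 84 lower. The split was 42 higher and 0 lower with median centring and 14 and 0 with the deposited ratios, and with median centring the median change of all probes was 0.18, against -0.02 as reported. Without control 1, 2 or 3 the count was 23, 45 or 52, and without hypoxic 1, 2 or 3 it was 18, 22 or 41. It was 3293 with only these groups in the fit, 4061 with array weights, 730 with probes detected on all 9 arrays and 608 without background correction.

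How much of the difference at the end of oxygen was still present 12 hours later could not be read from the overlap of calls against the control, which was 0 because limma called 0 in the first comparison. Across probes, the fold changes of hyperoxic and of P12.5 against the shared controls correlated at r = 0.381 (0.501 in simulations of unchanged groups), with a covariance of 0.0273 (simulated 0.0168). Part of the covariance may come from the shared controls, which were too few to be split. Without hyperoxic 1 the overlap was 383 and with array weights 950. The 383 also carry the split along the deposited reference, to which both hyperoxic arrays left in that fit belong. The calls of P12.5 against each labelled P12 group shared 161 probes of the same direction, 111 of them higher at P12.5. Independent lists of these sizes would share 3.53, a figure that ignores the shared P12.5 arrays. Simulations of unchanged groups gave 0, but with no change almost no probe is called, so they cannot judge this overlap. Across probes, which are not independent replicates, the fold changes of these comparisons correlated at r = 0.718 (simulated 0.498), with a covariance of 0.0682 (simulated 0.0166). Part of the excess may come from the shared P12.5 arrays, which were too few to be split.

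A further comparison, chosen after the data had been seen, set the P12.5 arrays against all 6 P12 arrays together. Its groups therefore did not depend on which P12 arrays were labelled control or hyperoxic. It was fitted separately, with 3 arrays against 6. Its tested probes were still those detected on all arrays of at least 1 labelled group. Its baseline joins normal and oxygen-exposed mice, so a difference is neither the change over room air nor the difference from normal. Where the P12 arrays differ among themselves, as for Pecam1, the value averages unlike contrasts. Hypoxia, gliosis and immediate early genes were among those that rose, and rod and cone genes among those that fell, though the cone list did not pass. The largest rises were in H2-Ab1 (2.30 ± 0.25), Ccl4 (at least 3.44-fold, adjusted p = 3.05e-05 by limma), Nupr1 (1.91 ± 0.31), Tnfrsf12a (1.86 ± 0.16), Igfbp3 (1.83 ± 0.20), H2-Q6 (at least 2.48-fold), Cdkn1a (1.75 ± 0.18) and H2-Q8 (1.64 ± 0.12), a close paralog of H2-Q6 whose probe may share its signal. The largest falls were in Arr3 (-1.94 ± 0.29, adjusted p = 0.00705 by limma), Slco1c1 (-1.46 ± 0.30), Peli3 (-1.38 ± 0.17), Guca1b (-1.19 ± 0.13), Slc17a1 (-1.15 ± 0.22), Gckr (-1.06 ± 0.17), Rdm1 (-1.05 ± 0.13) and the iron exporter Slc40a1 (-1.05 ± 0.25). Among the largest rises, H2-Q8 was detected on only 4 arrays of the study, so its size and place are uncertain, as for H2-Ab1 and Igfbp3. Adm rose by 1.24 ± 0.13 and Hmox1 by 1.25 ± 0.15, and both calls held under every alternative run on them. Vegfa at 0.70 ± 0.15 (adjusted p = 0.0367 by limma), Gfap at 0.58 ± 0.13 and Slc2a1 at 0.61 ± 0.11 passed too. These calls were lost under 10 of 18, 10 of 18 and 6 of 18 alternatives, and Vegfa passed in none of the planned comparisons. Angpt2 at 0.41 ± 0.10 (adjusted p = 0.0511 by limma), Pecam1 at -0.30 ± 0.42, Per2 at -0.12 ± 0.13 and Dbp at -0.19 ± 0.13 did not pass.

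By camera 11 lists passed against all 6 P12 arrays, 7 higher and 4 lower at P12.5. Of 38 HIF targets 13 rose, 0 fell and 25 did not pass, with 22 up and 3 down adjusted over the list alone, including Egln3 (1.41 ± 0.15) and Mt1 (1.57 ± 0.13), at a median of 0.46 (camera adjusted p = 2.79e-09; adjusted p = 0.1 with an estimated correlation). Of 19 glycolysis genes 3 rose, 0 fell and 16 did not pass, with 8 up and 1 down adjusted over the list alone, Pdk1 (1.25 ± 0.18), Hk2 (0.83 ± 0.16) and Slc2a1, at a median of 0.23 (camera adjusted p = 6.04e-04; adjusted p = 0.154 with an estimated correlation). Of 22 gliosis genes 8 rose, 0 fell and 14 did not pass, with 11 up and 0 down adjusted over the list alone, including Osmr (1.16 ± 0.16) and the cytokine signalling inhibitor Socs3 (0.97 ± 0.16), at a median of 0.38 (camera adjusted p = 7.18e-08, and 0.0333 with an estimated correlation). Of 20 immediate early genes 5 rose, 0 fell and 15 did not pass, with 5 up and 1 down adjusted over the list alone, including Ccn2 (1.24 ± 0.12), Fosl2 (1.17 ± 0.20), Jun (0.66 ± 0.13) and the phosphatase Dusp1 (0.50 ± 0.11), at a median of 0.23 (camera adjusted p = 3.58e-04; adjusted p = 0.154 with an estimated correlation). Of 26 genes of the unfolded protein and ATF4 response 2 rose, 0 fell and 24 did not pass, with 7 up and 1 down adjusted over the list alone, Stc2 (0.86 ± 0.10) and Shmt2 (0.73 ± 0.15), at a median of 0.27 (camera adjusted p = 0.00633; adjusted p = 0.1 with an estimated correlation). Of 8 inflammatory genes 2 rose, 0 fell and 6 did not pass, with 3 up and 1 down adjusted over the list alone, at a median of 0.22 (camera adjusted p = 0.0222; adjusted p = 0.297 with an estimated correlation), but the list did not pass without hyperoxic 1 (median 0.15). The 14 crystallins had a median of 1.70 (0.83 without hypoxic 1), with 0 passing over all probes and 0 up and 0 down adjusted over the list alone (camera adjusted p = 2.82e-04; adjusted p = 0.624 with an estimated correlation).

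Of 23 rod genes, 0 rose, 5 fell and 18 did not pass, with 0 up and 8 down adjusted over the list alone, including Gnat1 (-0.50 ± 0.10), Gnb1 (-0.51 ± 0.11) and the retinal transporter Abca4 (-0.57 ± 0.11). Of 12 pigment epithelium and melanocyte genes Pmel (-0.58 ± 0.13), Dct (-0.54 ± 0.13) and the retinol dehydrogenase Rdh5 (-0.51 ± 0.12) fell and 9 did not pass, with 0 up and 4 down adjusted over the list alone. Of 17 bipolar cell genes Lrtm1 (-0.58 ± 0.12) fell and 16 did not pass, with 0 up and 4 down adjusted over the list alone. None of 17 cholesterol synthesis genes passed over all probes, with 0 up and 2 down adjusted over the list alone. The medians were -0.12 for rods (camera adjusted p = 0.00599), -0.16 for bipolar cells (camera adjusted p = 0.0381) and -0.21 for cholesterol synthesis (camera adjusted p = 0.00599), and all 3 were positive with median centring (0.18, 0.11 and 0.06) and with the deposited ratios (0.15, 0.08 and 0.01), under which the median of all probes was 0.24 and 0.13. Relative to these shifts the medians lay lower, except that of rods with the deposited ratios, and all 3 lists passed as lower under both scalings. The bipolar list did not pass without hyperoxic 2, hyperoxic 3 or hypoxic 1. For the pigment epithelium the median was -0.32 (camera adjusted p = 0.0085), and -0.21 without hypoxic 3. It was -0.10 with median centring and -0.10 with the deposited ratios, before the same shifts are taken into account, and the list passed in all 3 settings. Over the alternatives run on lists the calls of rods, bipolar cells and inflammatory genes were lost under 2 of 19, 6 of 19 and 3 of 18. With an estimated correlation, the lists of rods, bipolar cells, cholesterol synthesis and pigment epithelium had camera adjusted p = 0.309, 0.537, 0.309 and 0.309.

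Against all 6 P12 arrays limma called 636 probes, 351 higher and 285 lower at P12.5, of which 259 and 124 changed at least 1.5-fold, in 421 genes (214 higher and 207 lower). Some gene calls were often lost under alternatives. Besides Vegfa and Gfap, the most frequent losses were 12 of 18 for Slc40a1, 11 of 18 for Rdh5 and Chrnb3, 10 of 18 for Tgfb2, Pmel, Dct, Dusp1, Calb1 and Gnb1, 9 of 18 for Slco1c1, Rdh10, Shmt2 and Vtn. The 161 probes called in the same direction against both labelled P12 groups were all among them. With median centring the split was 349 higher and 6 lower, and with the deposited ratios 33 and 0. The count was 233 without control 1, 404 without control 2, 1831, 1172 and 262 without hyperoxic 1, 2 and 3, and 97, 109 and 80 without hypoxic 1, 2 and 3. With array weights it was 4001 and with probes detected on all 9 arrays 993.

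The remaining 14 tested lists passed camera in none of these 4 comparisons. They were Muller glia, astrocytes, amacrine cells, horizontal cells, microglia and macrophages, oligodendrocytes and myelin, erythroid cells, angiogenic ligands and receptors, basement membrane, proliferation, NRF2 and antioxidant genes, circadian clock, p53 targets and cell death, and interferon-stimulated genes. Over their 221 memberships 0 genes passed between the arrays labelled hyperoxic and control, and 0 adjusted over the list alone. At P12.5, 8 rose and 4 fell against the arrays labelled hyperoxic (15 and 11 adjusted over the list alone, camera adjusted p = 0.273 to 0.799). Against those labelled control 8 rose and 3 fell (20 and 8 adjusted over the list alone, camera adjusted p = 0.224 to 0.971). Among the lists that did not pass, the median and the camera test differed in sign for 3 between the P12 groups, 0 and 6 at P12.5 against hyperoxic and control, and 3 against all 6 arrays. In no list that passed did they differ.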

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

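Alternatives were planned except the p-values as placed, normexp with offset 50, leaving out the 4 arrays in doubt, grouping by the deposited ratios and the comparison with all 6 P12 arrays, which were chosen after the data had been seen. Under the alternatives run on single genes and lists none passed in the other direction, but with the deposited grouping 3 lists called higher between the P12 groups passed as lower (medians -0.92 for endothelial, -0.46 for pericyte and -0.31 for heat shock genes, camera adjusted p = 1.16e-20, 1.67e-04 and 0.00706), and the other 5 did not pass. The endothelial list, lower against hyperoxic, passed as higher (median 0.17, camera adjusted p = 0.0292), and rods, cones, bipolar cells and cholesterol synthesis no longer passed there, nor did inflammatory genes against control. Most counts depended on the processing, and the cause was not tested. Over all named genes and lists and the alternatives run on them, 2756 values kept their side of the threshold, 781 lost a call and 67 gained one. Against all 6 P12 arrays, 56 of 60 named genes were called and 13 of them, all higher, held under every alternative run on single genes (normexp with offset 50, the p-values as placed, leaving out the 4 arrays and the deposited grouping were not run on them), as did 7 of 38 against hyperoxic and 4 of 33 against control.

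Between the P12 groups 0 probes became 2680 with array weights, 4359 without the 4 arrays in doubt (control 2 and 3, hyperoxic 2 and 3, so 1 array stayed per group and was assumed to vary like the P12.5 arrays) and 783 with the deposited grouping. The 333 probes against hyperoxic became 185 with median centring, 21 with the deposited ratios, 190 without the detection filter, where more probes share the adjustment, 5289 with array weights, 109 with only these groups, 7201 without the 4 arrays and 1229 with the deposited grouping. The 371 against control became 608 without background correction, 606 with normexp offset 50, 42 with median centring, 14 with the deposited ratios, 730 with detection on all 9 arrays, 4061 with array weights, 3293 with only these groups, 2584 without the 4 arrays and 1774 with the deposited grouping. The overlap of 0 became 950, 789 and 444 with array weights, without the 4 arrays and with the deposited grouping. The 636 against all 6 became 355 with median centring, 33 with the deposited ratios, 993 with detection on all 9 arrays, 4001 with array weights and 143 without the 4 arrays. The weights ranged from 0.118 (hyperoxic 1) to 4.12 (hyperoxic 3).

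Leaving out each array gave 0 to 568 probes between the P12 groups, 49 to 2006 against hyperoxic, 18 to 52 against control, 0 to 383 in the overlap and 80 to 1831 against all 6, the highest being without hyperoxic 1, except 52, which was without control 3. Lists passing between the P12 groups numbered 3 to 8, against 8 with all arrays. They numbered 5 with the deposited ratios, 1 with fry and 0 with an estimated correlation, which left 1 list, gliosis, in each comparison with P12.5.

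With the replicate number as a block, 127 probes passed against hyperoxic, 42 against control and 161 against all 6. The numbers share nothing known: 1 of 9 same-numbered pairs correlated over 0.1 (r = -0.339 to 0.105) and 2 of 9 arrays correlated best with their own number. Chip as a block was not possible, since no chip record was given. Signal over background limits what dim probes show.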

Other observations

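All tests in this part were chosen after the results had been seen. Muller glia genes moved both ways at P12.5 against all 6 P12 arrays. Of 24 tested, 3 rose, 3 fell and 18 did not pass, with 5 up and 6 down adjusted over the list alone. The metallothionein Mt2 (0.99 ± 0.12), Cp (0.61 ± 0.13) and the retinol dehydrogenase Rdh10 (0.55 ± 0.12) rose, and the water channel Aqp4 (-0.62 ± 0.11) was among those that fell. Among NRF2 and antioxidant genes Mt1 (1.57 ± 0.13) and Hmox1 (1.25 ± 0.15) rose and the mitochondrial peroxiredoxin Prdx3 (-0.54 ± 0.10) fell. The co-chaperone Bag3 (1.53 ± 0.11) rose in a heat shock list that did not pass. The horizontal cell gene Calb1 (-0.55 ± 0.13), the amacrine neuropeptide gene Tac1 (-0.47 ± 0.09) and the ganglion cell receptor Chrnb3 (-0.55 ± 0.13) fell. Of pericyte genes Zic1 (0.59 ± 0.11) rose and Vtn (-1.03 ± 0.23) fell, and of angiogenic ligands Tgfb2 (0.40 ± 0.09) rose.

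The 6 P12 arrays parted along the 3 arrays on which the deposited ratios are centred, not along their labels. Split that way 783 probes passed, and endothelial genes had a median of -0.92 in control 2, control 3 and hyperoxic 1 against the others (camera adjusted p = 1.16e-20; adjusted p = 0.00534 with an estimated correlation). A poor hyperoxic 1 array alone is argued against, since 923 probes passed without that array. The sex of the mice alone is argued against by balance, since each set of 3 held 1 array with the female pattern. With the sex pattern as a term 448 probes passed, which given this balance is no separate test of sex. The balance does not hold for the labelled groups, as the arrays with the female pattern were control 1, control 3 and hypoxic 2. An exchange of labels between 2 control and 2 hyperoxic arrays is a candidate explanation, as the deposited ratios had a median of 1 over the labelled controls at only 12.6% of probes, and all 3 p-value columns beside the control signals belong to the reference arrays. Batch and differences between individual mice bear on expression, not on where ratios are centred or p-value columns stand. As the whole account they are argued against, since the reference arrays had a median ratio of 1 at 100% of probes. Of the 3 p-value columns beside the hyperoxic signals, 0 belonged to those arrays. For the difference in expression itself batch and mouse differences stay open. No biological explanation was tested, and no array was given another condition here.

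Lens crystallins varied by several log2 units between arrays of 1 group. Lens tissue in some samples may account for this: over the 9 arrays the mean of the 14 crystallins followed that of the 3 tested lens genes outside the family (r = 0.900, exact permutation p = 0.000521; rho = 0.917, exact permutation p = 0.00131; 1 relation tested). Without hypoxic 1 and hyperoxic 1, the farthest from the median, r was 0.717. The mean of the 3 lens genes was 4.95 to 5.58 on all arrays but hypoxic 1 (6.44). That is near the level of undetected probes, such as H2-Q6 at 4.51 to 5.02 on the P12 arrays, which limits this relation. An effect of room air cannot be told apart from chance, as P12.5 lay 1.61 higher with an exact two-sided permutation p = 0.131 over 84 splits, whose smallest possible p is 0.0119. Retinal neurons and glia can also express crystallins, which was not tested.

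The P12.5 arrays also differ from P12 by 12 hours of clock time. A shift in the phase of the daily clock cannot be told apart from the effect of room air, since the design joins them. Against all 6 P12 arrays Dbp moved by -0.19 and Per2 by -0.12, but the clock genes Arntl (0.54), Usp2 (0.89) and Bhlhe40 (0.71) lay higher, of which only Bhlhe40, also a HIF target, was called. The bound of 0.5 on Arntl was set when its value was known. The 12 hours of age stay open and untested.

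Other splits of the same arrays were counted for each number of probes passing. For the P12 groups the real split gave 0, which each of the 10 splits reaches whatever the data, so this count shows nothing. The highest other was 783, along the deposited reference, the same structure of the samples as above. For P12.5 against hyperoxic the real split gave 333 and the highest other 0 (1 of 10 as large), and against control 371 and 2 (1 of 10). In these 3 comparisons the splits are too few for a share under 0.05. Against all 6 P12 arrays 2 of 84 splits gave as many as the real 636, the other being the deposited reference against the rest with 721. As this comparison was chosen after the data had been seen, that share does not exclude chance, nor a structure of the samples.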
